A study of Mus musculus with 22 samples.

How the data were processed

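RNA was measured in epithelial cells of mouse lung at embryonic day 18.5 (E18.5) and at 6 months, in 22 libraries. Per the labels' protocols, RNA was extracted with Trizol. The E18.5 cells were enriched on magnetic beads for EpCAM, an epithelial surface protein, with no gate against other cell types named. The 6-month cells were sorted by flow cytometry as EpCAM+, CD45− and CD31−, a gate that removes leukocytes (CD45) and endothelial cells (CD31). How the libraries were built, and whether reads kept their strand, is not given in the sources used here. Age and enrichment method therefore changed together, and no fold change was tested between the ages.

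The deposited files hold 1 value per Ensembl gene ID and library. The deposited log2 values run from 1 to 19.62 at E18.5 and from 1 to 21.19 at 6 months, and within an age all libraries share nearly the same set of values by rank: the SD between libraries at equal rank had a median of 0.00187 and 0.00242. The values were therefore taken as log2 expression quantile-normalized within each age. Per the submitters' processing notes, STAR, limma and the mouse build mm9 were used; their versions and roles are not given in the sources used here. The E18.5 files hold 13750 genes and the 6-month files 15958, of which 13034 are in both. Which filter chose these genes is not given in the sources used here. Symbols were taken from a GENCODE annotation on GRCm38, matched on gene ID, for 99.2% of the E18.5 IDs (13638) and 96.2% of the 6-month IDs (15353). Coordinates are GRCm38 from that annotation, not from mm9.

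Quantile normalization fixes some properties of these values. Every library's highest gene has the same value, so a difference in the most abundant genes, such as Sftpc, is a change of rank. A shift shared by most genes is removed. The read total of a library is not in the values. As a stand-in for depth, the distinct values at or below a library's median were counted, since genes with equal read counts are tied: there were 209 to 284 per E18.5 library and 128 to 382 per 6-month library, so neighbouring read counts of low genes can be told apart but total reads are unknown. The lowest value was held by 10 to 37 genes in an E18.5 library and by 4 to 201 in a 6-month library. It was read as 0 reads, which is inferred; where all libraries of a group had a gene at that value, no fold is given.

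Groups were taken from the labels. WT is NANCI +/+. NANCI is homozygous for the NANCI-CreERT2:RFP allele, Nkx is heterozygous for the Nkx2.1-GFP allele, and Double is heterozygous for both. At E18.5 there were 3 libraries in each of the 4 groups, and at 6 months 3 WT, 3 Nkx and 4 Double libraries. The labels do not say that the replicates are separate animals, so p-values measure the spread between these samples, which may be technical in part. The E18.5 WT, Nkx and Double and the 6-month WT and Nkx groups hold both sex patterns (given below). Each of these groups therefore holds more than 1 animal or pool of animals. For the E18.5 NANCI and 6-month Double groups the sex patterns do not tell. The 7 comparisons were fitted with limma 3.58.1 in R 4.3.3, with 1 model per age over all libraries of that age, group as the sole factor, and empirical Bayes moderation with a mean-variance trend. P-values were Benjamini-Hochberg adjusted over all genes tested, with a threshold of 0.05. The plan made before the data were examined assumed first that the files held counts, with a count model as the test, and named limma with trend for the case of log2 values; the files held log2 values, so limma was used. That plan also fixed the groups, the comparisons, the gene lists, the rule for named genes and a first set of alternatives. The difference of a genotype's effect between the ages was planned for counts alone and was not tested.

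Log2 fold changes are given with their standard error from limma, after ±; group levels are means of log2 values ± SD. Gene lists were tested with limma's camera, which asks whether a list moves against the other genes, with a preset inter-gene correlation of 0.01 and adjustment over the lists with at least 5 measured genes (25 at E18.5 and 26 at 6 months). Beside each list call stands the adjusted p obtained with a correlation estimated from the residuals, and the counts adjusted over the list alone. With the estimated correlation, the calls that held were those of leukocyte markers in E18.5 Nkx and Double against WT. The named genes are Nkx2-1 and the other genes of its locus in each comparison; the 6 largest changes in each direction among passing genes with a mean of at least 5 and a symbol that is not a gene-model name; and up to 4 passing members, by size, of each list that passed camera or had 2 passing members. The AT2, AT1, secretory and ciliated lists always entered, and where no member of a list passed, the 2 members with the highest mean were taken. Where fewer than 5 genes passed, the 5 smallest p-values were named. NANCI itself was not analysed here.

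The labels give the same replicate numbers to all groups. Deviations from the group means were correlated between same-numbered libraries; the numbers were taken to pair samples where each correlation was above 0.1. This held for E18.5 Double and Nkx (0.36, 0.56 and 0.23, each library correlating best with its own number), and the pairing comes from these values, not from the labels. It did not hold for the other 6 comparisons.

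The models were tested on simulated data made from the real genes, with 200 genes changed. Of 100 genes changed by 1 on the log2 scale, 65 were recovered for E18.5 NANCI against WT, 58 for E18.5 Nkx, 65 for E18.5 Double, 64 for E18.5 Double against Nkx, 55 for 6-month Nkx, 58 for 6-month Double and 64 for 6-month Double against Nkx. Of the 100 changed by 2, 83 to 94 were recovered, with 5 to 9 false calls per comparison. A simulated shift of 0.5 in the cell cycle list was called by camera in each comparison, and 1 other list was called, for 6-month Nkx. The simulated genes were independent, while the correlation estimated within real lists reached 0.629 at E18.5 and 0.774 at 6 months. The simulation therefore cannot show how often camera calls unchanged lists at such correlations.

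Alternatives were a minimum fold change, a fit of the compared groups alone, a replicate block, a sex covariate, repeated quantile normalization, an estimated correlation and the fry test for lists, and each library left out in turn. Further alternatives were added after seeing the data: a minimum mean of 5, cyclic loess, no variance trend, female or male libraries alone, a depth covariate, the block in a fit of both paired groups alone, an estimated correlation beside the block, and the overlap of calls under these settings. Sex was read from Xist and 4 Y-linked genes, since the labels do not give it. At E18.5, WT held 1 male and 2 female patterns, NANCI 3 male, and Nkx and Double each 1 male and 2 female. At 6 months, WT held 2 male and 1 female, Nkx 1 male and 2 female, and Double 4 female.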

Results

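The long noncoding RNA NANCI is transcribed next to Nkx2-1, the gene of a homeodomain transcription factor that specifies lung and thyroid epithelium. As its title states the question, the study asked how this gene pair keeps Nkx2-1 expression steady in the developing and adult lung. Lung epithelial cells were sequenced at E18.5, shortly before birth, from WT, NANCI, Nkx and Double mice (3 libraries each), and at 6 months from WT (3), Nkx (3) and Double mice (4). NANCI mice carried 2 copies of the NANCI-CreERT2:RFP allele, named for a tamoxifen-inducible Cre recombinase and a red fluorescent protein. Nkx mice carried 1 copy of the Nkx2.1-GFP allele, named for a green fluorescent protein, and Double mice 1 copy of each. Values are quantile-normalized log2 expression of 13750 genes at E18.5 and 15958 genes at 6 months. Library medians were 9.9 at E18.5 and 9.58 to 9.59 at 6 months, and read totals are unknown. Pearson correlations across genes between libraries were 0.91 to 0.985 at E18.5 and 0.859 to 0.977 at 6 months.

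Nkx2-1 (ENSMUSG00000001496; GRCm38 chromosome 12, 56531958 to 56536908, minus strand) lay between 14.48 and 14.95 in the 12 E18.5 libraries. Its log2 expression was 14.48, 14.84 and 14.93 in WT, 14.76, 14.84 and 14.89 in NANCI, 14.77, 14.73 and 14.95 in Nkx, and 14.84, 14.69 and 14.9 in Double libraries. Against WT the log2 fold change was 0.08 ± 0.14 in NANCI (limma adjusted p = 0.978), 0.07 ± 0.14 in Nkx (adjusted p = 0.82) and 0.06 ± 0.14 in Double (adjusted p = 0.842). At 6 months it was 14.17, 14.55 and 14.4 in WT, 13.96, 13.77 and 13.85 in Nkx, and 13.75, 13.97, 14.43 and 13.96 in Double libraries. The 3 Nkx libraries lay below the 3 WT libraries, but neither the Nkx difference (−0.52 ± 0.17, limma adjusted p = 0.128) nor the Double difference (−0.35 ± 0.16, adjusted p = 0.114) passed the threshold over all genes. Both differences stayed negative under each alternative, at −0.62 to −0.43 in Nkx and −0.48 to −0.26 in Double. Without Double replicate 3 the Double difference passed (−0.48, adjusted p = 0.0194); its adjusted p was 0.08 to 0.371 under the other alternatives. Which part of the gene the GFP allele replaces is not given in the sources used here, so reads from that allele may be counted and the level of Nkx2-1 does not check the Nkx labels. At E18.5 the sign of each of these 3 differences turned negative without WT replicate 1 (−0.05 in NANCI, −0.06 in Nkx and −0.07 in Double).

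**Figure D1:**
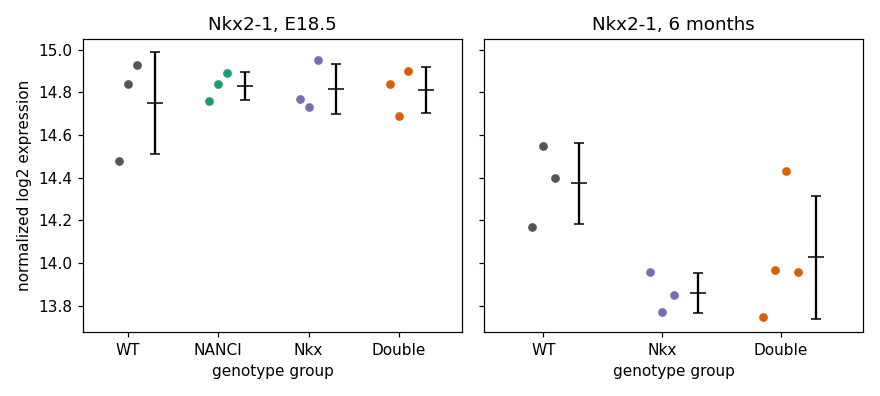
Normalized log2 expression of Nkx2-1 (y axis) in each library (points) by genotype group (x axis) at E18.5 and 6 months; the dash and bar give the mean and SD of the group. E18.5 libraries lie between 14.48 and 14.95, and the 6-month Nkx libraries, at 13.77 to 13.96, lie below the WT libraries.

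Of the neighbours of Nkx2-1 in the fixed locus list (7 genes measured at E18.5 and 9 at 6 months, Nkx2-1 included), few passed. Foxa1, which encodes a pioneer factor of endoderm, rose by 0.57 ± 0.13 on the log2 scale in E18.5 Double against WT (adjusted p = 0.013). In 6-month Double against WT, Nkx2-9, a homeobox gene next to Nkx2-1, rose by 2.58 ± 0.53 (adjusted p = 0.00298) and Mbip by 0.76 ± 0.21 (adjusted p = 0.014). Nkx2-9 was also higher in 6-month Double than in Nkx (1.68 ± 0.53, adjusted p = 0.0425).

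On principal components of all genes, the first component parted the libraries by genotype. At E18.5 it held 42.1% of the variance, with WT and NANCI libraries at −41.1 to −30.7 and Nkx and Double libraries at 22.4 to 57.5. At 6 months it held 51%, with WT at −67.5 to −58.5, Nkx at −33.1 to −23 and Double at 55.6 to 84.9.

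**Figure D2:**
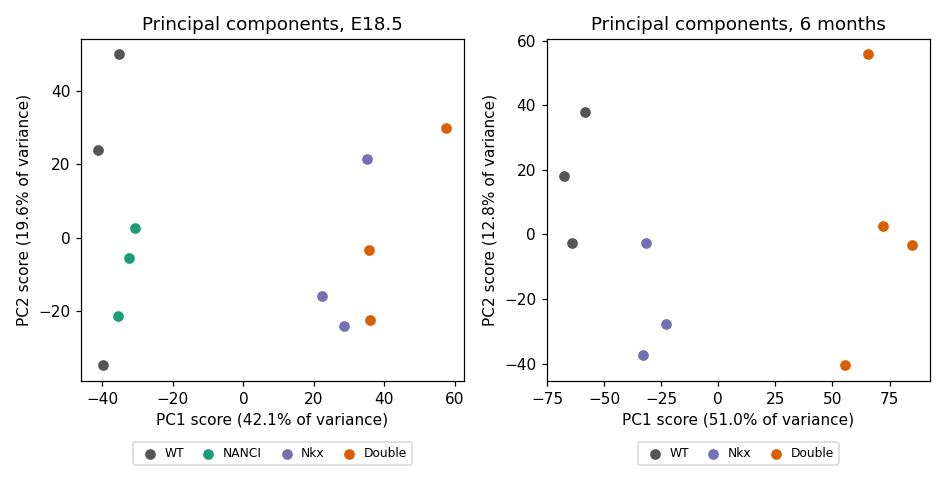
Scores of each library (points, coloured by genotype group) on the first (x axis) and second (y axis) principal component of all genes, at E18.5 and 6 months, with the percent of variance on each axis. WT and NANCI libraries lie at −41.1 to −30.7 on the first E18.5 component, apart from the Nkx and Double libraries at 22.4 to 57.5.

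The first comparison asked what the NANCI-CreERT2:RFP allele, in 2 copies, changes at E18.5. No gene differed between NANCI and WT libraries at the adjusted threshold in limma, while 426 of 13750 genes had an unadjusted p under 0.05. The smallest adjusted p was 0.0822. Of all genes, 6.27% had groups that did not overlap, where chance gives 10%. The gene with the smallest p was Esr1, which encodes estrogen receptor alpha: its log2 expression was 7.12 ± 0.48 in NANCI and 4.1 ± 0.09 in WT libraries (SD, n = 3 each), a difference of 3.02 ± 0.41 that did not pass in limma (adjusted p = 0.0822). Next came the gene model Gm13835 (1.33 ± 0.2, adjusted p = 0.115), Rab15 (0.86 ± 0.14, adjusted p = 0.16) and the ribosomal pseudogene Rpl30-ps11 (−1.7 ± 0.29, adjusted p = 0.202), whose reads can be shared with its parent gene. Prr16 was at each WT library's lowest value and at 3.53 ± 0.4 in NANCI (adjusted p = 0.259). Genes of the main epithelial types did not pass. The log2 fold change was 0 ± 0.31 for surfactant protein gene Sftpc and 0.06 ± 0.28 for phosphate transporter gene Slc34a2, both of AT2 cells, the surfactant-making cells of the alveolus. It was 0.21 ± 0.27 for Timp3 and 0.01 ± 0.18 for Emp2 in the list of AT1 cells, the flat gas-exchange cells, and 0.08 ± 0.25 for Scgb3a2 and −0.25 ± 0.33 for Scgb1a1 of secretory (club) cells.

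As lists, 9 of 25 passed camera in NANCI against WT with no member passing alone, and none held with an estimated correlation. Immediate early genes, transcription factors and regulators induced within minutes by stress or cell dissociation, lay lower (adjusted p = 9.87e-11, and adjusted p = 0.354 with an estimated correlation; 8 lower when adjusted over the list alone). Fos differed by −0.1 ± 0.21. Goblet cell and mucus genes lay higher (adjusted p = 3.86e-05, and adjusted p = 0.357 with an estimated correlation), with 14 of 15 members above 0 and 1 higher when adjusted over the list alone. Muc4, a membrane mucin gene, differed by 0.54 ± 0.33. Lists with lower values were p53 and Krt8 transitional state genes (adjusted p = 0.0049; adjusted p = 0.357 with an estimated correlation), the unfolded protein response (0.014; 0.393, with 1 lower over the list alone), mesenchymal markers (0.0184; 0.357), leukocyte markers (0.0225; 0.354) and ciliated cell genes (0.0269; 0.718), each pair in the same order. Nuclear-retained RNAs (0.0269; 0.43) and secretory cell genes (0.0369; 0.718) lay higher. Mean leukocyte marker expression was 6.72 to 7.13 in NANCI and 7.15 to 7.58 in WT libraries. The NANCI libraries were all of male pattern and 2 of 3 WT libraries female. With a sex covariate 4 lists passed in place of 9, and between male libraries alone, with 1 WT library, 11 genes and 5 lists. Leaving out WT replicate 2, WT replicate 3 or NANCI replicate 3 left 5 lists, and without WT replicate 2 or WT replicate 3, 1 and 2 genes passed.

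The second comparison asked what 1 Nkx2.1-GFP allele changes at E18.5. Genes of gut and goblet cells stood among the largest increases, and genes of AT2 cells and macrophages among those that fell. Tff3, a trefoil peptide of intestinal goblet cells, was at 10.68 ± 0.79 in Nkx and 2.59 ± 1.28 in WT libraries (n = 3 each; 1 WT library at its lowest value), a limma log2 fold change of 8.09 ± 0.69 (adjusted p = 8.75e-05). The gut peptide gene Guca2a rose by 7.26 ± 0.96 (adjusted p = 0.000797; 1 WT library at its lowest value), the carboxylesterase gene Ces1c by 6.24 ± 0.71, or 75.5-fold (adjusted p = 0.000332), the mucus protein gene Fcgbp by 6.04 ± 0.5, or 66-fold (adjusted p = 8.22e-05), Spink4 by 5.55 ± 0.57 and Ppp1r3a, a glycogen-targeting subunit of a phosphatase, by 4.87 ± 0.44. Among named genes with a mean of at least 5 over both groups, sex-linked genes aside, the largest decreases were in F13a1 (−5.7 ± 0.83; 1 Nkx library at its lowest value), Zmat4 (−4.41 ± 0.43), the macrophage mannose receptor gene Mrc1 (−4.01 ± 0.52), the guidance cue gene Ntn1 (−3.94 ± 0.33), Myom2 (−3.91 ± 0.75) and the scavenger receptor gene Stab1 (−3.73 ± 0.6). In all, 505 genes rose and 502 fell, 1007 of 13750 (7.32%), of which 559 by at least 1 on the log2 scale. The groups did not overlap in 22.2% of all genes, where chance gives 10%, and in 1004 of the 1007.

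Of 38 AT2 genes measured in Nkx against WT, 11 fell, 0 rose and 27 did not pass (17 lower when adjusted over the list alone). Among those that fell were the lysozyme gene Lyz2 (−2.52 ± 0.36, adjusted p = 0.00149), the calcium-binding protein gene S100g (−2.16 ± 0.28), Napsa, whose protease processes surfactant protein B (12.65 ± 0.31 against 14.68 ± 0.52; −2.03 ± 0.26, adjusted p = 0.0007), and Bex2 (−1.63 ± 0.25). The list passed camera (adjusted p = 2.19e-10), with adjusted p = 0.259 with an estimated correlation. AT1 genes went both ways: 1 of 36 rose and 5 fell (camera adjusted p = 0.696; the same counts over the list alone). Ndnf rose by 2.1 ± 0.17, and Rtkn2 (−1.95 ± 0.37), Pxdc1 (−1.18 ± 0.31) and Pdpn (−0.96 ± 0.24) fell. Of 27 secretory cell genes 5 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.0424, and adjusted p = 0.826 with an estimated correlation). With the depth covariate the median log2 fold change of this list was −0.05 in place of 0.27 and the call ended (adjusted p = 0.645). The gel-forming mucin gene Muc5b rose by 4.1 ± 0.89 (adjusted p = 0.0155) while Scgb1a1, the club cell secretoglobin, changed by −1.76 ± 0.33 (adjusted p = 0.00762). No ciliated gene of 35 passed, over all genes or over the list alone, though the list lay lower in camera (adjusted p = 6.43e-05, and adjusted p = 0.666 with an estimated correlation).

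Some mucus and gut genes rose in Nkx against WT at E18.5. Of 15 goblet genes, 8 rose and 0 fell (11 over the list alone; camera adjusted p = 2.76e-08, and adjusted p = 0.105 with an estimated correlation). Gcnt3, an enzyme of mucin glycosylation, and Tff2, a gastric trefoil peptide, were at the lowest value in each WT library and at 7.91 ± 0.09 and 5.89 ± 0.82 in Nkx, and Muc5ac, a gastric and airway mucin, rose by 2.82 ± 0.51 (adjusted p = 0.00537). Of 20 gastric and gut genes, 8 rose and 1 fell (9 and 2 over the list alone; camera adjusted p = 0.000452, and adjusted p = 0.105 with an estimated correlation). Hnf4a, a transcription factor of gut and liver, was at 6.31 ± 0.59 in Nkx and 1.89 ± 0.9 in WT, where 2 libraries were at their lowest value (adjusted p = 0.00212), and the membrane mucin gene Muc13 at 5.94 ± 1.03 with each WT library at its lowest value. The goblet list shares Tff2 with the gut list.

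Cell cycle genes rose as well in E18.5 Nkx against WT: 23 of 39 passed, all upward (28 over the list alone; camera adjusted p = 5.35e-18, and adjusted p = 0.105 with an estimated correlation). Mki67, the gene of the proliferation marker Ki-67, rose by 1.6 ± 0.22 (adjusted p = 0.00118), E2f8 by 1.66 ± 0.34, Ube2c by 1.6 ± 0.3 and Nusap1 by 1.51 ± 0.26. Leukocyte markers fell beside these groups: 7 of 14 fell and 1 rose (11 lower and 1 higher over the list alone), with the macrophage gene Adgre1 at −4.1 ± 0.66 (1 Nkx library at its lowest value), Cd53 at −3.34 ± 0.63 (likewise) and Ctss at −3.22 ± 0.86, and mean marker expression was 4.97 to 5.86 in Nkx and 7.15 to 7.58 in WT libraries. This list call held with an estimated correlation (camera adjusted p = 1.59e-06 without it and 0.028 with it). No gate against leukocytes is named for the E18.5 cells, so these markers may come from carried-over cells. Whether fewer such cells were carried over in Nkx libraries was not tested. Of 26 interferon-response genes 2 fell, Usp18 (−1.77 ± 0.23) and Ifit3 (−1.71 ± 0.42), with the same count over the list alone (camera adjusted p = 0.00707, and adjusted p = 0.312 with an estimated correlation). With the depth covariate this call ended too (median −0.14 in place of −0.29, adjusted p = 0.113). Single genes of other lists passed too. The chaperone gene Clu rose by 1.69 ± 0.33 and Klf5 by 0.86 ± 0.14, while the progenitor factor Sox9 (−0.77 ± 0.19), Id2 (−0.87 ± 0.15), the signalling gene Wnt3a (−1.73 ± 0.31) and the cell cycle inhibitor Cdkn1a (−1.14 ± 0.23) fell. The count of 1007 depended on single libraries: it was 466 without WT replicate 1, 611 without Nkx replicate 2, 502 without Nkx replicate 3 and 2179 without WT replicate 3. It was 491 in a fit of both groups alone and 5 between female libraries alone, 2 in each group.

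The third comparison asked what the combined heterozygous state changes at E18.5. In Double against WT, 981 genes rose and 1027 fell (2008, or 14.6% of those tested), of which 1075 by at least 1 on the log2 scale. The groups did not overlap in 27.2% of all genes, where chance gives 10%. Tff3 rose by 7.51 ± 0.69 (limma adjusted p = 5.16e-05), Guca2a by 7.09 ± 0.96, the matrix protein osteopontin (Spp1) by 7.04 ± 0.62 (adjusted p = 4.09e-05) and Syt8 by 6.38 ± 0.56, each with 1 WT library at its lowest value. The desmosomal gene Pkp1 rose by 5.99 ± 0.44, or 63.5-fold (adjusted p = 1.82e-05), and Ern2, a sensor of endoplasmic reticulum stress in mucous cells, by 5.88 ± 0.46, or 58.9-fold. By the same minimum mean, the largest decreases were in F13a1 (−5.15 ± 0.83), the lysosomal protease gene Ctss (−4.77 ± 0.86), Zmat4 (−4.46 ± 0.43), Myom2 (−4.41 ± 0.75), Cped1 (−3.94 ± 0.61) and Slc10a6 (−3.72 ± 0.8); Ctss, Myom2 and Slc10a6 were at the lowest value in 1 Double library.

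AT2 genes fell in Double: 25 of 38 fell, 0 rose and 13 did not pass (31 lower over the list alone; camera adjusted p = 6e-17, and adjusted p = 0.117 with an estimated correlation). The log2 fold change was −2.76 ± 0.36 for Lyz2, −2.68 ± 0.28 for S100g, −2.23 ± 0.26 for Napsa (adjusted p = 0.000196) and −2.02 ± 0.42 for the lipid desaturase gene Scd1. Mean AT2 expression was 13.5 to 13.99 in Double, 13.97 to 14.4 in Nkx and 14.56 to 14.96 in WT libraries. Of 36 AT1 genes 7 fell and 1 rose (the same over the list alone; camera adjusted p = 0.0551). Rtkn2 changed by −2.44 ± 0.37, Pxdc1 by −1.44 ± 0.31, Pmp22 by −1.12 ± 0.2 and Ndnf by 1.77 ± 0.17. Of 35 ciliated genes 14 fell and 0 rose (24 over the list alone; camera adjusted p = 1.05e-10, and adjusted p = 0.3 with an estimated correlation), among them the tubulin gene Tuba1a (−1.06 ± 0.24) and Dynlrb2 (−1.03 ± 0.24). Secretory genes went both ways: 6 of 27 rose and 2 fell (9 and 4 over the list alone; camera adjusted p = 0.215). Muc5b rose by 4.26 ± 0.89 and Scgb3a1 by 2.58 ± 0.8, while Scgb1a1 changed by −3.1 ± 0.33 (adjusted p = 0.000128) and Upk3a by −2.71 ± 0.55. Of 38 genes of fatty acid and cholesterol synthesis 8 fell and 2 rose (13 and 2 over the list alone; camera adjusted p = 0.000341, and adjusted p = 0.401 with an estimated correlation). Fads1 changed by −1.2 ± 0.26 and the elongase gene Elovl6 by 2.12 ± 0.42.

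Goblet genes rose in E18.5 Double (9 of 15, 0 fell; 10 over the list alone; camera adjusted p = 1.27e-06, and adjusted p = 0.127 with an estimated correlation). Muc5ac rose by 4.05 ± 0.51 (adjusted p = 0.000282), and Gcnt3 stood at 7.74 ± 0.66 in Double libraries. Of 20 gut genes 9 rose and 1 fell (10 and 2 over the list alone; camera adjusted p = 0.000326, and adjusted p = 0.113 with an estimated correlation). Hnf4a stood at 6.7 ± 0.74 in Double and at 1.89 ± 0.9 in WT libraries. Cell cycle genes rose: 31 of 39, 0 fell (35 over the list alone; camera adjusted p = 7.46e-25, and adjusted p = 0.0704 with an estimated correlation). Mki67 rose by 2.17 ± 0.22 (adjusted p = 8.62e-05) and E2f8 by 2.39 ± 0.34. Of 10 basal cell genes 3 rose and 1 fell (camera adjusted p = 0.182). The keratin gene Krt17 rose by 3.01 ± 0.58. Of 8 mesothelial genes 3 rose and 2 fell (camera adjusted p = 0.298). Upk3b rose by 3.24 ± 0.53 and Msln by 1.18 ± 0.28. Immediate early genes rose in 5 of 25 cases (8 over the list alone; camera adjusted p = 0.00152, and adjusted p = 0.462 with an estimated correlation). Egr2 rose by 1.41 ± 0.32 and Nr4a1 by 0.87 ± 0.26.

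Leukocyte markers fell in E18.5 Double. Of 14, 10 fell and 0 rose (10 lower and 1 higher over the list alone), with Adgre1 at −4.17 ± 0.66 (1 Double library at its lowest value) and Mrc1 at −3.64 ± 0.52. The call held with an estimated correlation (camera adjusted p = 6.78e-07 without it and 0.0232 with it), and mean marker expression was 4.93 to 5.5 in Double libraries. As in Nkx, whether fewer leukocytes were carried over was not tested. Of 26 interferon-response genes 7 fell (9 over the list alone; camera adjusted p = 0.000101, and adjusted p = 0.117 with an estimated correlation), among them Ifit2 (−1.55 ± 0.31). Of 8 MHC class II genes, which present antigen, 2 fell (7 over the list alone; camera adjusted p = 0.000341, and adjusted p = 0.191 with an estimated correlation). H2-Aa changed by −1.64 ± 0.29 and Cd74 by −1.3 ± 0.35. Of 13 endothelial markers 3 fell (camera adjusted p = 0.0551). Esam changed by −1.51 ± 0.25, Tek by −1.41 ± 0.38 and Kdr by −0.88 ± 0.18. The count of 2008 was 1182 without WT replicate 1, 1222 without Double replicate 2 and 1330 without Double replicate 3. It was 928 in a fit of both groups alone and 84 between female libraries alone.

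Nkx and Double calls against WT overlapped at E18.5: 444 genes rose in both, 441 fell in both and 0 went opposite ways. Independent lists of these sizes would share 36 higher and 37.5 lower genes. In 20 simulated sets of unchanged groups against 1 simulated WT group, 0 genes were shared. Groups drawn without a difference seldom give a call, so simulated counts of shared genes set no baseline for the overlap. The simulated genes were also drawn independently of each other. Fold changes correlated across genes with r = 0.89 (0.5 simulated), and their covariance was 0.41 against 0.05 simulated, a difference of 0.36. These simulated groups were independent, while same-numbered Nkx and Double libraries are paired. With their mean correlation of 0.38 simulated as well, r was 0.69, the covariance 0.07 (a difference of 0.34) and at most 1 gene was shared. The 3 WT libraries cannot be split with 2 on each side, so part of the excess may come from the shared controls. The overlap of 885 was 426 without WT replicate 1, 565 without Nkx replicate 2, 473 without Nkx replicate 3 and 1748 without WT replicate 3.

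The fourth comparison asked what the added NANCI allele changes in embryos that carry the Nkx2.1-GFP allele. In limma 1 gene passed, Mucl3, a mucin-like gene: 11.49 ± 0.47 in Double and 9.31 ± 0.32 in Nkx libraries (SD, n = 3 each), a log2 fold change of 2.18 ± 0.24, or 4.52-fold (adjusted p = 0.0127). At an unadjusted p under 0.05 there were 559 genes. Double and Nkx libraries did not overlap in 8.6% of all genes, where chance gives 10%. Next by p were Spp1 (4.21 ± 0.62, adjusted p = 0.103), Syt8 (3.61 ± 0.56, adjusted p = 0.117), Plekha6 (1.38 ± 0.25, adjusted p = 0.256) and Gm13835 (1.06 ± 0.2, adjusted p = 0.256). With the replicate number as a block the full fit also called 1 gene, and a blocked fit of both groups alone, chosen after seeing the data, called 9 (7 higher and 2 lower). These were Mucl3, Spp1, Syt8, Plekha6, H19 (2.14 ± 0.2), Sprr1a (3.13 ± 0.32) and Tub (1.69 ± 0.19), higher in Double, and Gm13394 (−6.23 ± 0.27) and Scgb1a1 (−1.34 ± 0.13). The call of Mucl3 ended without Nkx replicate 1, Nkx replicate 3, Double replicate 2 or Double replicate 3, which left 0 genes, between female libraries alone, and in a fit of both groups alone without the block. That fit called Gm13394, Spp1 and Syt8.

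As lists, 11 of 25 passed camera in E18.5 Double against Nkx with no member passing alone in the fit without the block, and none held with an estimated correlation. AT2 genes lay lower (adjusted p = 3.49e-13; adjusted p = 0.17 with an estimated correlation; 37 of 38 members below 0 and 1 lower over the list alone), as did ciliated genes (adjusted p = 9.11e-11; 0.231), AT1 genes (9.55e-05; 0.324), lipid synthesis genes (1.89e-05; 0.231), interferon-response genes (0.00187; 0.195) and MHC class II genes (1.8e-05; 0.17, with 1 lower over the list alone), each pair in the same order. Cell cycle genes lay higher (adjusted p = 3.56e-20; adjusted p = 0.17 with an estimated correlation). Of its 39 members 38 were above 0, with Mki67 at 0.56 ± 0.22. So did immediate early genes (1.8e-09; 0.17), unfolded protein response genes (0.000106; 0.17), basal cell genes (0.00232; 0.17, with 3 higher over the list alone) and p53 and Krt8 transitional state genes (0.0346; 0.392, with 1 higher over the list alone). Leukocyte markers did not pass (adjusted p = 0.0735) and lay at 4.93 to 5.5 in Double and 4.97 to 5.86 in Nkx libraries. With the replicate block they passed, lower in Double (adjusted p = 0.0322, and 0.0393 in the blocked fit of both groups alone, where mesothelial markers passed too, higher, with adjusted p = 0.0172). With an estimated correlation beside the block neither list passed (adjusted p = 0.225 for both, and 0.338 for both in the fit of both groups alone).

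**Figure D3:**
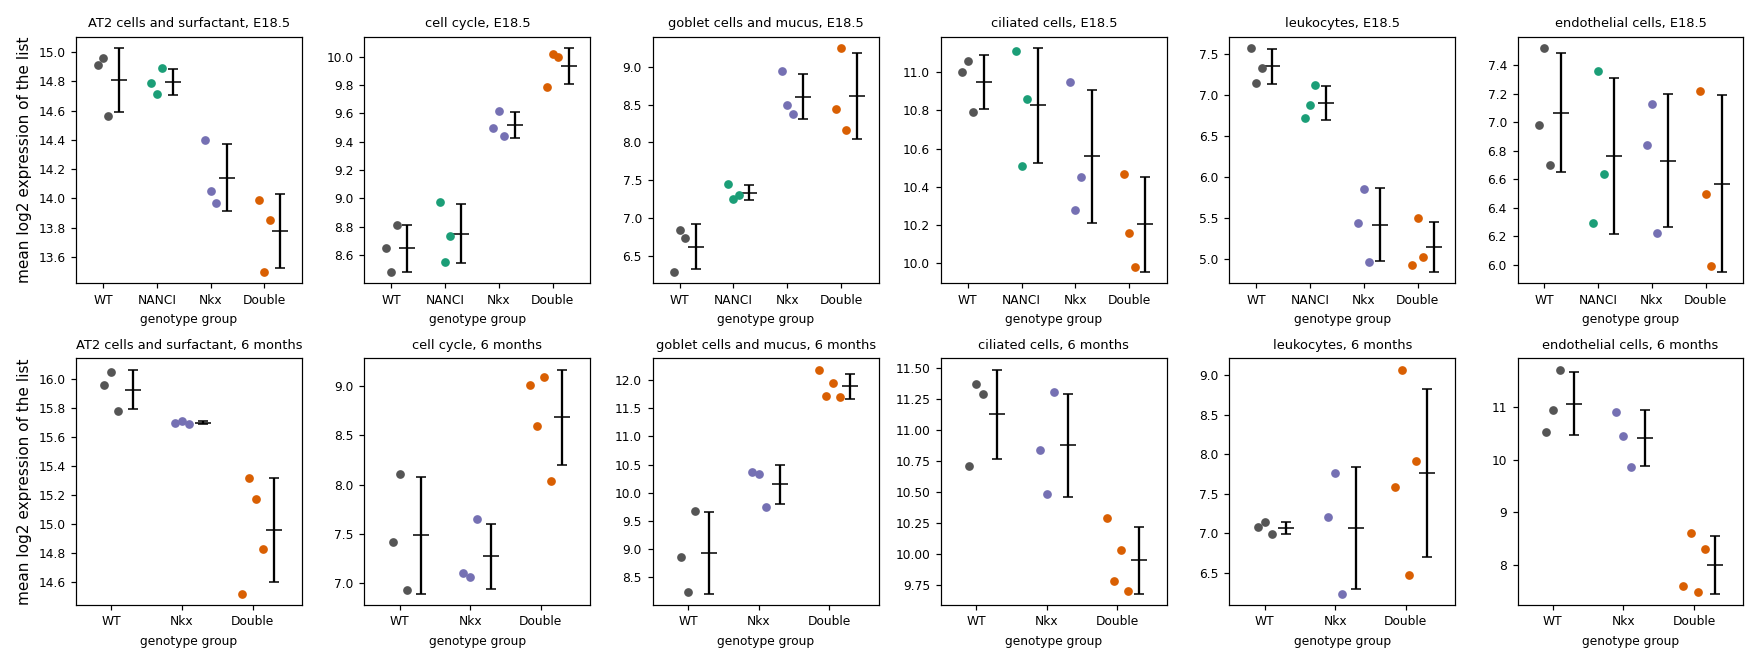
Mean normalized log2 expression (y axis) of 6 fixed gene lists in each library (points) by genotype group (x axis), at E18.5 (upper panels) and 6 months (lower panels); the dash and bar give the mean and SD of the group. Leukocyte markers lie at 4.93 to 5.86 in the E18.5 Nkx and Double libraries against 7.15 to 7.58 in WT, and endothelial markers at 7.48 to 8.61 in the 6-month Double libraries against 10.52 to 11.71 in WT.

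At 6 months the comparison of Nkx with WT asked what the Nkx2.1-GFP allele alone changes in the adult. Some digestive, mucous and secretory genes rose, in lists whose calls were lost with an estimated correlation, and the genes that fell most included thyroglobulin. Cym, the gene of the gastric protease chymosin, rose by 4.77 ± 1.01 (limma adjusted p = 0.0347), Ppp1r3a by 4.44 ± 0.36, or 21.8-fold (adjusted p = 0.00049), the secreted cytokine-like gene Retnla by 3.99 ± 0.71, or 15.9-fold (adjusted p = 0.02), Gp2 by 3.86 ± 0.9, Veph1 by 3.28 ± 0.31 (adjusted p = 0.00105) and Ambp by 3.23 ± 0.53. The log2 fold change was −4.59 ± 0.54 for the receptor tyrosine kinase gene Ros1 (adjusted p = 0.0029) and −3.82 ± 0.78 for Tg, the gene of thyroglobulin, the thyroid hormone precursor (adjusted p = 0.0305). Klk14 (−3.8 ± 0.51), Shisa6 (−3.7 ± 0.74; 2 Nkx libraries at their lowest value), Avpr1a (−3.68 ± 0.82) and Bcan (−3.29 ± 0.61) fell as well. In all, 242 genes rose and 177 fell (419, or 2.63% of 15958), of which 201 by at least 1 on the log2 scale. The groups did not overlap in 30.5% of all genes, where chance gives 10%.

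Of 18 goblet genes, 7 rose and 0 fell in 6-month Nkx against WT (11 over the list alone; camera adjusted p = 2.79e-07, and adjusted p = 0.388 with an estimated correlation). Tff2 rose by 2.85 ± 0.51 (adjusted p = 0.02) and Agr2, a protein disulfide isomerase needed for mucin folding, by 2.2 ± 0.49 (adjusted p = 0.0416). Of 32 gut genes 5 rose (8 over the list alone; camera adjusted p = 3.99e-05, and adjusted p = 0.388 with an estimated correlation). The transthyretin gene Ttr rose by 3.97 ± 0.61 (1 WT library at its lowest value), the pepsinogen gene Pgc by 3.17 ± 0.44 (adjusted p = 0.00677) and Hnf4a by 2.45 ± 0.51 (adjusted p = 0.0339). Of 30 secretory genes 6 rose (16 over the list alone; camera adjusted p = 4.25e-10, and adjusted p = 0.388 with an estimated correlation). Scgb3a2 rose by 1.85 ± 0.36 and Gsto1 by 1.72 ± 0.3. WT replicate 3 came close to the Nkx level: mean secretory expression was 13.62 in it, 12.61 and 12.29 in the other WT libraries and 13.65 in the lowest Nkx library, and mean goblet expression 9.68, 8.87, 8.25 and 9.74 in that order. Of the AT2 genes, Bex2 fell (−2.4 ± 0.32, adjusted p = 0.00574), Itih4 rose (1.75 ± 0.29) and 36 of 38 did not pass (4 higher and 1 lower over the list alone; camera adjusted p = 0.0238, and adjusted p = 0.662 with an estimated correlation). No AT1 gene of 36 passed, with the receptor gene Ager at 0.15 ± 0.46 (camera adjusted p = 0.0338, higher; adjusted p = 0.662 with an estimated correlation), and no ciliated gene of 35 (camera adjusted p = 0.00482, lower; adjusted p = 0.662 with an estimated correlation). The p53 and Krt8 transitional list rose in 2 of 32 cases (6 higher and 1 lower over the list alone; camera adjusted p = 0.000679, and adjusted p = 0.49 with an estimated correlation). The tight junction gene Cldn4 rose by 1.73 ± 0.26.

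Smaller list calls in 6-month Nkx against WT were also lost with an estimated correlation. Lipid synthesis genes lay lower (camera adjusted p = 0.0238; adjusted p = 0.662 with an estimated correlation). Acaca changed by −0.9 ± 0.2 and Elovl5 by 0.73 ± 0.13 (1 higher and 5 lower over the list alone). Inflammatory genes lay higher (adjusted p = 0.0406; adjusted p = 0.662 with an estimated correlation). The prostaglandin synthase gene Ptgs2 changed by 1.22 ± 0.22 and Csf1 by −1.74 ± 0.35 (3 higher and 1 lower over the list alone). The unfolded protein response lay higher too (adjusted p = 0.0357; adjusted p = 0.582 with an estimated correlation), with Asns by 1.09 ± 0.16 (4 higher and 1 lower over the list alone). Endothelial markers lay lower without a passing member (camera adjusted p = 6.88e-05; adjusted p = 0.662 with an estimated correlation): all 24 were below 0, with Pecam1 at −0.49 ± 0.43, and library means were 9.85 to 10.91 in Nkx and 10.52 to 11.71 in WT. Mesenchymal markers did likewise (adjusted p = 0.00741; adjusted p = 0.662 with an estimated correlation). The count of 419 fell in each fit without 1 library: 178 without WT replicate 1, 59 without WT replicate 2, 211 without WT replicate 3, 75, 65 and 144 without Nkx replicates 1, 2 and 3, and lists passing numbered 7 in place of 12 without WT replicate 2. WT held 2 libraries of male pattern and Nkx 1. With a sex covariate 228 genes passed, between female libraries alone (1 WT library) 4, and without the variance trend 98. Of the 12 list calls, 4 ended with the sex covariate: AT2 (adjusted p = 0.0503, median −0.27 in place of −0.33), lipid synthesis (0.127, −0.09 in place of −0.21), inflammatory (0.0595, 0.33 in place of 0.41) and unfolded protein response genes (0.0899, 0.11 in place of 0.13). Immediate early (0.024, median 0.38 in place of 0.23) and nuclear-retained genes (0.0402, −0.65 in place of −0.68) passed with this covariate and not in the fit without it.

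Of the 7 comparisons, most genes passed between Double and WT at 6 months, the comparison of adults carrying both alleles with adults carrying neither. Of 15958 genes, 2937 rose and 2858 fell (5795, or 36.3%), of which 2843 by at least 1 on the log2 scale. The groups did not overlap in 40.1% of all genes, where chance gives 5.71%. Retnla was at 19.34 ± 1.15 in Double (n = 4) and 11.2 ± 1.37 in WT (n = 3), a limma log2 fold change of 8.13 ± 0.66 (adjusted p = 9.19e-06). The lubricin gene Prg4 rose by 8.05 ± 0.49, or 265-fold (adjusted p = 1.53e-06), Syt8 by 7.93 ± 0.6, the stomach and bladder antigen gene Psca by 7.76 ± 1.07, and the cornified envelope gene Sprr2a3 (8.99 ± 0.89) and the apolipoprotein gene Apoa1 (7.67 ± 0.77) rose from 2 WT libraries at their lowest value. Sprr2a3 belongs to a family of near-identical genes whose reads can be shared. Among named genes with a mean of at least 5 over both groups, sex-linked genes aside, the largest decreases were in Bcan (−5.79 ± 0.57), Cntfr (−5.34 ± 0.43), the peroxisomal gene Acoxl (−5.27 ± 0.28, adjusted p = 6.75e-07), Ppp1r1a (−4.87 ± 0.59; 1 Double library at its lowest value), Mrc2 (−4.63 ± 0.42) and Ros1 (−4.58 ± 0.51).

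Goblet and gut genes rose in 6-month Double against WT. Of 18 goblet genes 14 rose and 0 fell (the same over the list alone; camera adjusted p = 1.49e-08, and adjusted p = 0.336 with an estimated correlation). Agr2 was at 12.95 ± 0.54 in Double and 6.23 ± 1.2 in WT libraries (6.73 ± 0.46, or 106-fold, adjusted p = 2.81e-06), Muc5b rose by 5.87 ± 0.46, or 58.4-fold, and Tff2 by 5.71 ± 0.48. Of 32 gut genes 22 rose and 3 fell (22 and 4 over the list alone; camera adjusted p = 1.1e-07, and adjusted p = 0.336 with an estimated correlation). Hnf4a rose by 6.76 ± 0.48, or 108-fold (adjusted p = 3.93e-06), and Dmbt1 by 7.17 ± 0.75. Of 30 secretory genes 13 rose and 1 fell (14 and 1 over the list alone; camera adjusted p = 0.00352, and adjusted p = 0.535 with an estimated correlation); Gsto1 rose by 4.12 ± 0.28 and the airway defence gene Bpifa1 changed by −4.35 ± 1. Of the p53 and Krt8 transitional genes 19 of 32 rose and 3 fell (20 and 3 over the list alone; camera adjusted p = 4.82e-05, and adjusted p = 0.336 with an estimated correlation). Tnip3 rose by 4.74 ± 0.26, Cldn4 by 3.02 ± 0.25 and the keratin gene Krt19 by 2.36 ± 0.21. Cell cycle genes rose in 26 of 39 cases and fell in 1 (32 and 1 over the list alone; camera adjusted p = 7.36e-07, and adjusted p = 0.529 with an estimated correlation). The mitotic kinase gene Plk1 rose by 3.8 ± 0.29. Progenitor genes went both ways (9 of 30 rose and 8 fell; camera adjusted p = 0.828): Clu changed by 5.89 ± 0.38 and Etv5 by −2.41 ± 0.35.

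Genes of the alveolar and ciliated cells fell in 6-month Double. Of 38 AT2 genes 23 fell and 4 rose (24 and 4 over the list alone; camera adjusted p = 2.33e-06, and adjusted p = 0.37 with an estimated correlation). Napsa was at 13.44 ± 0.53 in Double and 16.19 ± 0.14 in WT libraries (−2.75 ± 0.24, adjusted p = 1.3e-05), and Bex2 (−3.53 ± 0.3) and Etv5, a transcription factor of AT2 cells (−2.41 ± 0.35), fell too. Of 36 AT1 genes 17 fell and 4 rose (19 and 4 over the list alone; camera adjusted p = 0.00312, and adjusted p = 0.535 with an estimated correlation). Igfbp2 changed by −3.76 ± 0.62, Spock2 by −3 ± 0.46 and Rtkn2 by −2.69 ± 0.65. Of 35 ciliated genes 30 fell and 0 rose (the same over the list alone; camera adjusted p = 6.18e-12, and adjusted p = 0.336 with an estimated correlation). Hydin changed by −2.19 ± 0.26 and Foxj1, the regulator of motile cilia, by −1.78 ± 0.22 (12.09 ± 0.33 against 13.87 ± 0.25, adjusted p = 0.00013). Of 38 lipid synthesis genes 24 fell and 4 rose (27 and 4 over the list alone; camera adjusted p = 1.4e-06, and adjusted p = 0.336 with an estimated correlation), with the acetyl-CoA carboxylase gene Acaca at −1.95 ± 0.18. Immediate early genes fell in 16 of 27 cases and rose in 1 (the same over the list alone; camera adjusted p = 5.95e-05, and adjusted p = 0.37 with an estimated correlation). Egr3 changed by −3.12 ± 0.68 and Klf2 by −2.03 ± 0.2.

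**Figure D4:**
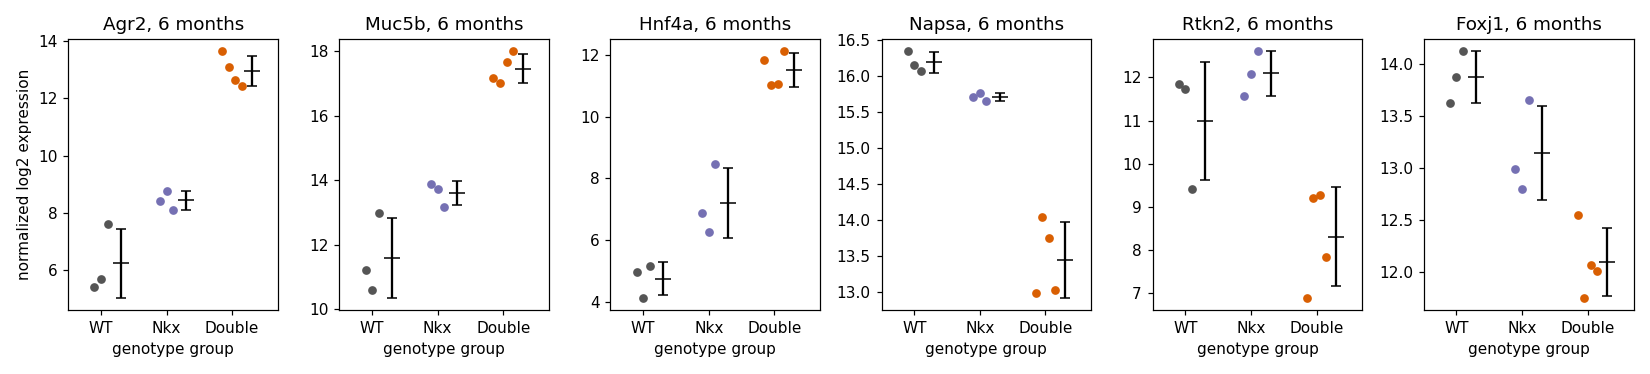
Normalized log2 expression (y axes, each with its own range) of 6 genes in each 6-month library (points) by genotype group (x axis); the dash and bar give the mean and SD of the group. Agr2, Muc5b and Hnf4a are higher and Napsa and Foxj1 lower in each Double library than in each WT library, with Agr2 at 12.95 ± 0.54 in Double and 6.23 ± 1.2 in WT.

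At 6 months all 24 endothelial markers fell in Double against WT (camera adjusted p = 1.4e-16, and adjusted p = 0.336 with an estimated correlation; 24 over the list alone). Plvap changed by −3.84 ± 0.35 (adjusted p = 1.68e-05) and Eng by −3.75 ± 0.42. Library means were 7.48 to 8.61 in Double and 10.52 to 11.71 in WT, in cells sorted as CD31−. Of 29 mesenchymal markers 24 fell and 0 rose (26 over the list alone; camera adjusted p = 1.25e-11, and adjusted p = 0.336 with an estimated correlation). Tcf21 changed by −3.7 ± 0.31 and Pdgfra by −3.56 ± 0.35. Leukocyte markers went both ways, 2 up and 2 down of 24 (camera adjusted p = 0.329). Cd68 changed by 1.64 ± 0.34 and Csf1r by −1.16 ± 0.19. Of 9 mesothelial markers 6 fell and 2 rose (camera adjusted p = 0.0978). Upk3b changed by −3.21 ± 0.62. Of 33 interferon-response genes 9 rose and 2 fell (the same over the list alone; camera adjusted p = 0.0215, and adjusted p = 0.664 with an estimated correlation). Oas1a rose by 2.8 ± 0.37. Of 10 MHC class II genes 6 fell and 0 rose (the same over the list alone; camera adjusted p = 0.029, and adjusted p = 0.535 with an estimated correlation), and of 30 unfolded protein response genes 14 rose and 3 fell (15 and 3 over the list alone; camera adjusted p = 0.00859, and adjusted p = 0.336 with an estimated correlation). The Double libraries were all of female pattern and WT held 1 female library. With a sex covariate 3851 genes passed, and 2297 between female libraries alone, where the single WT library is assumed to vary like the other groups. The list calls of AT1 (adjusted p = 0.155, median −0.21 in place of −0.56), secretory (0.21, 0.32 in place of 0.53) and interferon-response genes (0.432, 0.23 in place of 0.42) ended with the sex covariate. Among female libraries these and the MHC class II call ended (the latter at 0.0585, median −0.84 in place of −0.88), and inflammatory genes passed (0.0241, 0.83 in place of 0.41).

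The last comparison asked what the added NANCI allele changes in adults that carry the Nkx2.1-GFP allele. In Double against Nkx, 1629 genes rose and 1831 fell (3460, or 21.7%), of which 1846 by at least 1 on the log2 scale. Double and Nkx libraries did not overlap in 31.8% of all genes, where chance gives 5.71%. Prg4 rose by 7.53 ± 0.49, or 185-fold (limma adjusted p = 1e-05), Sprr2a3 by 7.2 ± 0.89, the chitinase-like gene Chil4 by 6.14 ± 0.81, Syt8 by 6.11 ± 0.6, the phospholipase gene Pla2g4c by 6.06 ± 0.35, or 66.8-fold (adjusted p = 8.02e-06), and Spink1 by 5.86 ± 0.61 (1 Nkx library at its lowest value). Igfbp2 (−4.5 ± 0.62), Cst8 (−4.34 ± 0.58), Gpm6a (−4.32 ± 0.43), Acoxl (−4.1 ± 0.28, adjusted p = 1.23e-05), Ogn (−3.88 ± 0.46) and Hes2 (−3.83 ± 0.42) fell most by the same measure. Goblet genes rose (12 of 18, 0 fell; 14 and 1 over the list alone; camera adjusted p = 7.18e-07, and adjusted p = 0.274 with an estimated correlation). Agr2 rose by 4.52 ± 0.46 (adjusted p = 0.000136), Muc5b by 3.87 ± 0.46 and Muc5ac by 3.27 ± 0.31. Gut genes rose in 15 of 32 cases and fell in 3 (19 and 3 over the list alone; camera adjusted p = 8.34e-07, and adjusted p = 0.273 with an estimated correlation). Dmbt1 rose by 5.65 ± 0.75 and Vsig1 by 4.56 ± 0.48. Cell cycle genes rose (26 of 39, 0 fell; 34 and 1 over the list alone; camera adjusted p = 9.79e-12, and adjusted p = 0.362 with an estimated correlation). Plk1 rose by 3.7 ± 0.29 and Mki67 by 2.84 ± 0.63.

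Between Double and Nkx at 6 months, 14 of 38 AT2 genes fell and 2 rose (20 and 2 over the list alone; camera adjusted p = 3.17e-06, and adjusted p = 0.362 with an estimated correlation). Napsa changed by −2.27 ± 0.24 and Lamp3, a marker of lamellar bodies, by −1.83 ± 0.31. Of 36 AT1 genes 17 fell and 3 rose (19 and 3 over the list alone; camera adjusted p = 2.51e-06, and adjusted p = 0.362 with an estimated correlation). Rtkn2 changed by −3.79 ± 0.65 and Spock2 by −3.31 ± 0.46, and Hopx, a homeobox gene of AT1 cells, changed by −1.79 ± 0.28. Ciliated genes fell (26 of 35, 0 rose; 28 over the list alone; camera adjusted p = 7.41e-12, and adjusted p = 0.362 with an estimated correlation). Sntn changed by −1.86 ± 0.29. Secretory genes went both ways (3 of 30 rose and 5 fell, as over the list alone; camera adjusted p = 0.618). Retnla changed by 4.15 ± 0.66 and Bpifa1 by −3.77 ± 1. Lipid synthesis genes fell in 14 of 38 cases and rose in 2 (22 and 3 over the list alone; camera adjusted p = 4.01e-06, and adjusted p = 0.362 with an estimated correlation). Immediate early genes fell in 15 of 27 cases (21 lower and 1 higher over the list alone; camera adjusted p = 3.73e-09, and adjusted p = 0.274 with an estimated correlation), and p53 and Krt8 transitional genes rose in 14 of 32 and fell in 3 (15 and 4 over the list alone; camera adjusted p = 0.00158, and adjusted p = 0.362 with an estimated correlation). All 24 endothelial markers fell (24 over the list alone; camera adjusted p = 3.86e-18, and adjusted p = 0.274 with an estimated correlation). Plvap changed by −2.92 ± 0.35. Also lower were 17 of 29 mesenchymal markers (24 over the list alone; camera adjusted p = 2.47e-11, and adjusted p = 0.274 with an estimated correlation) and 6 of 9 mesothelial markers, of which 1 rose (6 and 2 over the list alone; camera adjusted p = 0.00942, and adjusted p = 0.273 with an estimated correlation). Leukocyte markers did not pass as a list (2 up and 2 down of 24; camera adjusted p = 0.28). The count of 3460 was 2204 without Nkx replicate 1 and 1998 between female libraries alone.

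At 6 months, Nkx and Double calls against WT shared 227 higher and 160 lower genes, and 1 gene went opposite ways. Independent lists would share 44.5 and 31.7. In 20 simulated sets of unchanged groups 0 genes were shared, which sets no baseline here either, since such groups seldom give a call. Fold changes correlated across genes with r = 0.61 (0.53 simulated), with a covariance of 0.36 against 0.07 simulated, a difference of 0.29. Part of the excess may come from the WT libraries both comparisons use. The overlap of 387 was 164, 55 and 195 without WT replicates 1, 2 and 3, and 74, 61 and 139 without Nkx replicates 1, 2 and 3.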

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

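No test in this part was chosen after its result was seen; each value below met a rule set for all named genes and lists. Among 196 groups of values in the 6-month Double libraries, 5 had 1 library whose gap to the nearest other, as a share of the group's range, was above Dixon's 95% critical value for 4 libraries. Chance gives about 1 in 20 groups, more than were found. Ppp1r3a was lowest in Double replicate 2 at 10.81, with 11.07 to 11.11 in the others (gap ratio 0.847). Ptgs2 was lowest in replicate 1 at 11.9, against 12.48 to 12.59 (0.841). Cd68 was highest in replicate 2 at 11.06, against 9.59 to 9.64 (0.968). Klf4 was highest in replicate 4 at 10.96, against 10.17 to 10.26 (0.884). Sntn was highest in replicate 1 at 9.57, against 8.56 to 8.73 (0.83). These libraries differ from gene to gene.

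For 237 genes and for the list means, every library of a genotype was compared with every WT library of its age, to find values that moved one way at E18.5 and the opposite way at 6 months. The difference between the ages was not tested, since the tables of the ages were normalized separately and the cells enriched differently. In Double against WT the log2 fold changes at E18.5 and 6 months were −1.08 and 2.13 for the noncoding RNA Meg3, −0.36 and 1.85 for Ddc, 1.42 and −1.33 for the WNT inhibitor gene Wif1, 1.6 and −3.29 for the matrix gene Dcn, 3.24 and −3.21 for Upk3b and 2.19 and −1.72 for Upk1b. For immediate early genes they were 1.41 and −1.19 for Egr2, 0.75 and −2.28 for Fosb and 0.92 and −2.03 for Klf2, and for the macrophage gene Cd68 −0.41 and 1.64. For the mean of the mesothelial list the differences were 0.76 and −1.08, though that list passed camera at neither age (adjusted p = 0.298 and 0.0978), and for the mean of the immediate early list 0.47 and −0.84. In Nkx against WT they were −0.96 and 0.92 for Pdpn, −1.13 and 1.59 for the cytokine gene Lif, −1.13 and 1.22 for Ptgs2 and −0.93 and 1.8 for Lyz1.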

How the results depend on the processing

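The minimum mean, cyclic loess, no variance trend, single-sex and depth settings, the block in a fit of both paired groups or with an estimated correlation and all settings of the overlaps were chosen after seeing the data. Of the named-gene values under the alternatives, 5137 kept direction and side of the threshold, 801 lost the call, 1 gained it (Nkx2-1 in 6-month Double against WT without Double replicate 3) and 10 reversed, all 10 for Nkx2-1 at E18.5, which passed under no setting at that age. The losses were uneven: in 6-month Nkx against WT 118 of 222 values lost the call with 1 library left out, 24 of 37 without the trend, 18 of 37 with the block and 35 of 37 in female libraries, where 59 of 63 were lost for E18.5 Nkx and 76 of 91 for E18.5 Double. Counts of calls, list calls and overlaps stayed within 1.5 times in 199 cases, were lower beyond that in 66 and higher in 9. Repeated quantile normalization, a minimum mean of 5 and cyclic loess kept each of these counts within that range. The values were already quantile-normalized, so repeating that step hardly changes them and is no test of the normalization, though it enters the counts above. With a log2 fold change of at least 1, counts were 559 (E18.5 Nkx), 1075 (E18.5 Double), 201 (6-month Nkx), 2843 (6-month Double) and 1846 (6-month Double against Nkx), fewer by construction. Fitting the compared groups alone, with fewer residual degrees of freedom, gave 491 (Nkx), 928 (Double), 3 (Double against Nkx) and an overlap of 407 at E18.5. Female libraries alone, fewer by construction, gave 5 for E18.5 Nkx, 84 for E18.5 Double, 0 for E18.5 Double against Nkx, 4 for 6-month Nkx, 2297 for 6-month Double, 1998 for 6-month Double against Nkx, and overlaps of 5 and 4; male libraries alone gave 11 genes and 5 lists for NANCI. For the other settings the cause was not tested. The sex covariate gave 228 for 6-month Nkx, 3851 for 6-month Double, a 6-month overlap of 199 and 4 lists for NANCI. Without the trend there were 3 calls for NANCI, 98 for 6-month Nkx and a 6-month overlap of 92. With the depth covariate there were 3 calls for E18.5 Double against Nkx (Mucl3, Plekha6 and Spp1). Lists passing with an estimated correlation were 0 (NANCI), 1 (Nkx), 1 (Double) and 0 (Double against Nkx) at E18.5, and 0 in each 6-month comparison. With fry they were, in the same order, 0, 6 (all camera calls but secretory and ciliated), 11 and 0 at E18.5. At 6 months they were 1 (Nkx), 14 (Double) and 13 (Double against Nkx).

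Besides these 2 list tests and fits without 1 library, settings ended 40 list calls and gave 34 others; none of the lists gained passed with an estimated correlation in the fit of all groups. Lost ones not given beside the results follow (median log2 fold change without and with the setting, adjusted p with it). In NANCI against WT the secretory call ended with cyclic loess (0.08, 0.09, p 0.0671), depth (0.08, −0.06, p 0.895), male libraries (0.08, −0.04, p 0.701) and the block (0.08, 0.08, p 0.0538), the leukocyte call with depth (−0.36, −0.38, p 0.0614) and sex (−0.36, −0.42, p 0.119), the nuclear-retained call with sex (0.39, 0.4, p 0.157), and with male libraries and with sex the ciliated (−0.15, −0.19, p 0.0859, and −0.15, −0.02, p 0.671), unfolded protein response (−0.09, −0.15, p 0.0859, and −0.09, −0.08, p 0.151) and mesenchymal calls (−0.39, −0.42, p 0.285, and −0.39, −0.4, p 0.258). In E18.5 Nkx the secretory call ended with cyclic loess (0.27, 0.22, p 0.0516), no trend and the block (0.27 in each, p 0.0554 and 0.0601). E18.5 Double against Nkx lost basal genes with female libraries (0.24, 0.15, p 0.0759) and p53 and Krt8 genes with these and with a minimum mean (0.12, 0.06 in each, p 0.0906 and 0.119). In 6-month Nkx the unfolded protein response call ended with cyclic loess (0.13, 0.11, p 0.0658) and no trend (0.13, 0.13, p 0.054), the inflammatory call with depth (0.41, 0.25, p 0.108), no trend and the block (0.41 in each, p 0.056 and 0.0516), the AT1 call with no trend (0.22, 0.22, p 0.0546), and with female libraries the AT2 (−0.33, −0.12, p 0.314) and lipid synthesis calls (−0.21, 0.02, p 0.901). In 6-month Double the AT1 (−0.56, −0.1, p 0.224), secretory (0.53, 0.11, p 0.93) and interferon-response calls (0.42, 0.27, p 0.299) ended with female libraries. Of the gained calls (median above and below 0) depth gave 6 (3 and 3), female libraries 7 (3 and 4), a minimum mean 5 (all below), both groups alone 6 (2 and 4), the block 5 (1 and 4), the block with both groups alone 2 (1 and 1), sex 2 (1 and 1) and cyclic loess 1 (below). Among them were leukocyte markers in E18.5 Double against Nkx with depth (p 0.0401), female libraries (p 0.0305), a minimum mean (p 0.00875) and the block, at 0.231 with an estimated correlation, endothelial markers there with a minimum mean (p 0.0463), and the locus list with depth in E18.5 Nkx (p 0.0451) and Double (p 0.0143).

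With 1 library left out at a time, counts ranged from 0 to 2 (NANCI), 466 to 2179 (E18.5 Nkx), 1182 to 2691 (E18.5 Double), 0 to 1 (E18.5 Double against Nkx), 59 to 211 (6-month Nkx), 4445 to 5727 (6-month Double) and 2204 to 3492 (6-month Double against Nkx), in the same order lists from 5 to 10, 7 to 10, 10 to 13, 11 to 14, 7 to 15, 14 to 16 and 12 to 14, and overlaps from 426 to 1748 at E18.5 and 55 to 426 at 6 months. The lowest counts came without WT replicate 1 (466 and 1182), WT replicate 2 (59 and 4445) and Nkx replicate 1 (2204), the highest E18.5 counts without WT replicate 3. The log2 fold change of Nkx2-1 changed sign or came to 0 at E18.5, where it was within its standard error: in NANCI it ran from −0.05 (without WT replicate 1) to 0.17 with 1 library left out, and was 0.34 (adjusted p = 0.311) in male libraries. In Nkx it ran from −0.06 (without WT replicate 1) to 0.16, was 0 without Nkx replicate 3, and was −0.13 in female libraries. In Double it ran from −0.07 (without WT replicate 1) to 0.15 and was −0.12 in female libraries. In Double against Nkx it ran from −0.05 to 0.06 (without Nkx replicate 3), was 0.05 without Double replicate 2, 0 with cyclic loess and 0.01 in female libraries.

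With the replicate number as a block, E18.5 counts were 0 (NANCI), 1090 (Nkx), 2155 (Double) and 1 (Double against Nkx, and 9 in a blocked fit of both groups alone). At 6 months they were 131 (Nkx), 5072 (Double) and 2285 (Double against Nkx). Overlaps were 970 and 123. Correlations of same-numbered libraries were −0.31 to −0.01 (NANCI, WT), −0.2, 0.51 and 0.42 (E18.5 Nkx, WT) and −0.21, 0.48 and 0.05 (E18.5 Double, WT). At 6 months they were −0.31 to −0.11 (Nkx, WT), −0.08 to 0.1 (Double, WT) and −0.07 to 0.12 (Double, Nkx). In none of these did each library correlate best with its own number. E18.5 Nkx replicates 2 and 3 and Double replicate 2 did so with WT. For E18.5 Double against Nkx no list call changed with the block except those of leukocyte and mesothelial markers; of the 9 genes of the blocked fit of both groups alone, Gm13394, Spp1 and Syt8 also passed in that fit without the block, and Mucl3 in the fit of all groups. Planned for counts and not run were a second count model, its calls for the overlap, relative log expression factors, voom, a pseudocount of 0.1, and the difference between the ages under any setting; no low-count filter equals the values as used. Read totals are unknown, and differences in genes near the lowest value rest on few reads.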

Other observations

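Calls of the same genotype were compared across the ages, where no library is shared, over 13034 genes measured at both. For Double against WT, 538 genes rose at both ages and 613 fell at both, where independent lists would share 188 and 180, and 90 went opposite ways (r = 0.51 across genes, which are not independent replicates). For Nkx against WT, 48 rose and 41 fell at both, where independent lists would share 8.06 and 5.82, and 3 went opposite ways (r = 0.24). Genes named at both ages include Ppp1r3a (4.87 ± 0.44 and 4.44 ± 0.36 in Nkx), Hnf4a (4.42 ± 0.68 and 2.45 ± 0.51 in Nkx), Syt8 (6.38 ± 0.56 and 7.93 ± 0.6 in Double) and Napsa (−2.23 ± 0.26 and −2.75 ± 0.24 in Double).

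The following genes were chosen after their values were seen. H19 and Igf2, imprinted neighbours expressed in fetal growth, were higher at E18.5 in Nkx (3.23 ± 0.45, limma adjusted p = 0.0013, and 1.4 ± 0.26, adjusted p = 0.00661) and in Double against WT (5.37 ± 0.45, adjusted p = 4.09e-05, and 2.7 ± 0.26, adjusted p = 6.47e-05). H19 was at 14.37 to 16.25 in Nkx, 17.03 to 18.45 in Double and 11.81 to 12.67 in WT libraries. Igf2 was at 14.62 to 15.27, 15.95 to 17.03 and 13.48 to 13.73 in the same order. Between Double and Nkx neither passed (2.14 ± 0.45, adjusted p = 0.419, and 1.3 ± 0.26, adjusted p = 0.321), though H19 did with the replicate block in a fit of both groups alone (2.14 ± 0.2, adjusted p = 0.0152). At 6 months Igf2 did not pass in Nkx (−0.4 ± 0.51, adjusted p = 0.682) or Double against WT (−0.82 ± 0.48, adjusted p = 0.201), at 6.86 to 7.94, 5.48 to 7.68 and 7.56 to 7.9 in Nkx, Double and WT libraries; H19 has no 6-month value. Esr1 was at 6.6 to 7.55 in NANCI and 5.75 to 6.89 in Double libraries at E18.5, and at 3.99 to 4.15 in WT and 3.81 to 4.74 in Nkx. At 6 months it was at 8.35 to 8.66 in Double, 4.95 to 6.61 in WT and 5.15 to 6.4 in Nkx libraries (Double against WT 2.64 ± 0.41, adjusted p = 0.000506). The libraries above the rest at both ages are those whose labels name the NANCI-CreERT2:RFP allele, whose ERT2 part derives from an estrogen receptor; whether reads of that allele were counted to Esr1 was not tested. In the E18.5 Nkx library with a male pattern, Xist, the RNA that silences an X chromosome in females, was at 11.34, against 7.21 to 8.48 in the other male-pattern libraries of that age and 14.64 to 16.94 in the female ones.

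The tests that follow had their outcomes stated before the results were seen, except that the depth covariate was added as a setting after seeing the data, and the test of the fold with it at E18.5 was chosen after its calls were seen. Each count of calls was set against other splits of the same libraries into groups of the same sizes. For 6-month Double the real and highest other counts were 5795 and 1255 against WT, and 3460 and 915 against Nkx. In both only the real split of 35 gave as many. This excludes chance at the 0.05 level only if each library is a separate animal, which is unknown. The other comparisons allow 10 splits, too few for a share under 0.05. Their real and highest other counts were 1007 and 928 for E18.5 Nkx, 2008 and 1 for E18.5 Double, and 419 and 4 for 6-month Nkx, each with 1 split as large, 0 and 1 for NANCI with 10 as large, and 1 and 8 for E18.5 Double against Nkx with 5 as large. Of the 4 splits of the latter that part all 3 pairs, the highest other gave 1, as the real one did. The split with 928 calls exchanges WT replicate 3 with Nkx replicate 2 and points to a structure of the samples: on the second E18.5 component, WT replicates 1 and 2 (23.9 and 50.1) and Nkx replicate 2 (21.6) lie apart from WT replicate 3 (−35) and the other Nkx libraries (−15.9 and −24.2).

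The first pattern weighed is the lower endothelial and mesenchymal markers in 6-month Double sorts. Sex and depth are argued against as the whole cause: with a sex covariate the median endothelial log2 fold change was −3.86 (−3.22 without it, and −4.08 to −3.49 with 1 library left out), and with a depth covariate −3.15 (−3.34 to −2.78). A candidate explanation is that fewer endothelial cells were carried over into the Double sorts, although the CD31 gate should remove them. Of 28 measured endothelial markers outside the fixed list, 100% were lower in Double (26 passing, median −2.86), among them the abundant Ptprb (13.3 in WT and 9.65 in Double) and Thbd (13.12 and 9.76), and Pecam1, which encodes CD31, changed by −2.92 ± 0.4. Fewer cells would give this, but an effect of genotype on the endothelium would as well, so these markers do not favour either; the effect of genotype stays open and untested, and other values of these libraries were not corrected for such cells.

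The second pattern is the parting of the E18.5 libraries by the Nkx2.1-GFP allele. The E18.5 Nkx and the 6-month Double fold changes, which share no library, had a Pearson r of 0.43 across 13034 genes (0.39 to 0.44 with 1 library left out). Between the Nkx fold changes of both ages r was 0.24. This argues against an E18.5 batch whose effects are unrelated to the 6-month changes. A batch that shifted the mix of cells the same way would also give a positive r, so the test cannot exclude a batch. Genes within 20 Mb of Nkx2-1 were called at 0.956 times the share elsewhere (9 of 128 against 994 of 13510, with a 95% Clopper-Pearson interval of 0.444 to 1.76 from the near genes, and p = 1 in Fisher's exact test, two-sided). This argues against strain variants carried with the allele that mainly change genes near it. Variants that act on distant genes, or that lie elsewhere in the genome, would not raise this share, so they stay open. Depth as the whole cause is argued against: with a depth covariate, which moved the other genes by a median of 0.12, the median log2 fold change of the 1007 Nkx calls, taken in the direction of the call, was 1.05 and without it 1.08 (0.98 times, and 0.92 to 0.99 times with 1 library left out), and for the 2008 Double calls 1.03 and 1.05 (0.94 to 1.01 times). Whether depth adds to single calls stays open: of the Nkx calls 71.2% remained, and with 1 library left out 25.7% to 96.7% of those of the same libraries, while the median standard error was 0.24 in place of 0.23.

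The third pattern is the higher cell cycle expression in E18.5 Nkx libraries, for which delayed maturation may be an explanation. Outside the cell cycle list, the Nkx fold change then should oppose the step from E18.5 NANCI to 6-month WT libraries. Across 12995 genes Pearson r was −0.11, but it ran from −0.24 to 0.02 with 1 library left out, and the step also holds the change of enrichment method and of table. The test therefore decides nothing, and delayed maturation stays open.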
